A study of Danio rerio with 12 samples.

How the data were processed

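Gene expression was measured on 12 Affymetrix zebrafish arrays, 2 for each of 6 groups: vehicle control and TCDD, each unamputated, at 6 hours and at 7 days after amputation. Each array carries RNA pooled from the ventricle apex of 10 hearts, so that p-values measure the spread between these pools and not between single fish. Groups and replicate numbers were taken from the sample labels, which list the controls as untreated, while the protocol names a vehicle injection.

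The main table holds the authors' deposited intensity values, 1 per probe set and array, made with RMA per the submitters' processing notes; the RMA software and its version, and whether all arrays were normalized in 1 run, are not given in the sources used here. RMA subtracts background, equalises the distributions of the arrays and summarises the probes of a probe set. The deposited intensities are on a linear scale, as their range shows, and log2 was taken before any test. The upper part of the distribution is not equal on all arrays, as the report states, and the deposited values were analysed as they stand. A further set of 5 tables holds the authors' own comparisons, made with GenePattern's Comparative Marker Selection per the file headers. Each compares 1 group with a class called the rest, whose arrays the headers do not name. Both tables named for 6 hours write their class with a 7 in the header, and the group was taken from the table name and checked on the class means. In them the score is a t statistic, per the file headers. The p-value is from permutations and is also given after Benjamini-Hochberg adjustment, per the file headers. The fold is a ratio of class means that is never under 1 in the deposited tables. These tables were used only for the counts quoted from them.

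Of 15617 probe sets, 115 Affymetrix controls were left out and 15502 were tested, with no filter on dim values. The tables carry no detection calls, so a level near the median of an array is not shown to be above background, and a change from or to it is at best a lower bound. GEO's platform annotation, with symbols updated through a RefSeq gene table, gave 1 gene symbol to 10795 tested probe sets, several to 135 and none to 4572; the gene of 10711 was found in the RefSeq table. A total of 8793 genes had a probe set, 1539 of them more than 1. Genes are named only from probe sets with 1 symbol, and for most named genes whose other probe sets differ in call these are given. An older symbol matched 2 list entries to unrelated genes, and both were removed from the lists after their values had been seen.

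A linear model with 6 group means was fitted to the log2 values of all 12 arrays with limma 3.58.1 in R 4.3.3, so that the groups share 1 estimate of the spread. It has 6 residual degrees of freedom, to which the moderation of limma's eBayes added 2.87. From it 10 comparisons were drawn: TCDD against control at each of the 3 times, each amputated group against the unamputated group of the same treatment, the 2 interactions between TCDD and amputation, and the mean TCDD effect over the 3 times. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and a probe set was called at an adjusted p below 0.05. Errors after ± beside a log2 fold change are limma's standard errors, and those beside a group level are standard deviations of 2 arrays. The median standard error of a comparison of 2 groups was 0.243 log2 units. An exact permutation test of 2 arrays against 2 cannot give a p below 0.333, so only the model was used. The number of arrays limits the precision of every value.

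A further 27 lists of genes (pathways, and markers of the cell types of the heart and of neighbouring tissues) were tested on 1 probe set per gene, the one with the highest mean, where at least 5 genes were measured. The competitive test camera was run with a preset correlation of 0.01 and again with an estimated correlation, and the self-contained test fry, which asks whether a list's genes move on balance in 1 direction, beside them. For each list the members that passed are counted over all probe sets and also adjusted over the list alone. The groups, comparisons, gene lists, tests, the rule for named genes and most of the alternatives were chosen before the data were examined.

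Named genes are the 8 rises and the 8 falls with the largest log2 fold change among those that passed and in which both arrays of 1 group lay above both arrays of the other. Clone names were skipped. Up to 4 passing members of a list were added, or, where none passed, the 2 with the smallest p. A further 12 genes were fixed whatever their result; of these cyp1b1, cyp1c2, ahrra and ahrrb had no named probe set.

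The alternatives chosen at the same time were quantile normalization, centring of each array on its median, leaving out the 25% dimmest probe sets, eBayes with trend and robust settings, array weights, 1 probe set per gene, a further limit of 1 on the absolute log2 fold change, adjustment over all 10 comparisons together, a fit of only the arrays of the groups compared, the replicate number as a block, and leaving out each array in turn. Leaving out TCDD 6 hpa replicate 1 also from comparisons it has no part in, a block within each time and a covariate for epidermal markers were added after the data were seen. In a fit that leaves 1 array in a group, that array is assumed to vary like the other groups.

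The fit and the list test were tested on simulated data drawn from the unamputated control level and the residual spread of each of the 15502 probe sets, with 200 of them changed, 50 by each size. For TCDD against control at 7 days it found 22 of 50 changes of 1 log2 unit, 42 of 2, 49 of 3 and 50 of 4, and called 15 unchanged probe sets. For control at 7 days against unamputated control it found 23, 39, 48 and 49 and called 6 unchanged probe sets, and for the mean TCDD effect 42, 48, 50 and 50 and called 12. A further simulation for control at 7 days, on 8793 genes, raised the extracellular matrix list by 1 log2 unit. Camera with the preset correlation called it and 0 of the other 26 lists. The simulated genes varied independently of each other, while the correlation estimated from the data was 0.65 for oxidative phosphorylation genes. The simulation therefore does not show how often the preset correlation gives false list calls in these data. Each probe set was also simulated with the same spread on all arrays, while in the data TCDD 6 hpa replicate 1 stood apart. The shares of changes found may thus not carry over to the data. Each comparison was simulated once, so the unchanged probe sets called give no error rate. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.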

Results

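The series followed the adult zebrafish ventricle through the first week after amputation of its tip, in fish of the AB strain given a vehicle or TCDD at 70 ng/g by injection into the body cavity 1 day before surgery. TCDD, a dioxin, is a high-affinity ligand of the aryl hydrocarbon receptor (AHR), a transcription factor, and the series addresses how it affects regeneration of the heart. The tissue was the lower piece of the ventricle, which after surgery holds the amputation plane and the regenerate. It was taken from unamputated fish (0 hpa), 6 hours after amputation (6 hpa) and 7 days after amputation (7 dpa). There were 2 arrays in each of the 6 groups, each from 1 pool of 10 hearts, and each array gave values for 15502 probe sets besides controls.

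TCDD 6 hpa replicate 1 stood apart from the other arrays in several measures, and it bears on every comparison through the shared spread. Control 0 hpa replicate 2 stood apart in 2 control probe sets (8.55 and 10.04, at most 2.85 and 2.75 elsewhere), and the 4 arrays at 7 dpa in the DapX spike control. The BioB control lay at 8.45 and 9.87 on replicate 2 of control and TCDD 7 dpa, and at 5.72 to 7.37 on the other arrays. The median log2 intensity ran from 3.26 to 3.53. Within 5 groups the 2 arrays correlated across probe sets at r = 0.958 to 0.979, and within TCDD 6 hpa at r = 0.901. TCDD 6 hpa replicate 1 had 202 probe sets more than 1 log2 unit above and 461 more than 1 log2 unit below all other arrays. Its 99th percentile was 9.88 against 10.41 to 10.64 on the others. The 3′ minus 5′ log2 difference of the actin control probe sets, which grows when RNA is degraded, was 3.35 on this array. It was 1.36 to 2.07 on the other replicate 1 arrays and −0.08 to 1.29 on the replicate 2 arrays. That of gapdh was 1.12 on this array against 0.52 to 1.96 on all others and 1.35 to 1.96 on the other replicate 1 arrays. Of 8 epidermal marker genes above a log2 intensity of 5 on some array, the median lay 2.18 and 0.94 above the unamputated control mean on the 2 arrays of TCDD 7 dpa, −0.16 and 0.61 from it on those of control 7 dpa, and 0.83 and −0.10 from it on those of control 6 hpa.

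**Figure D1:**
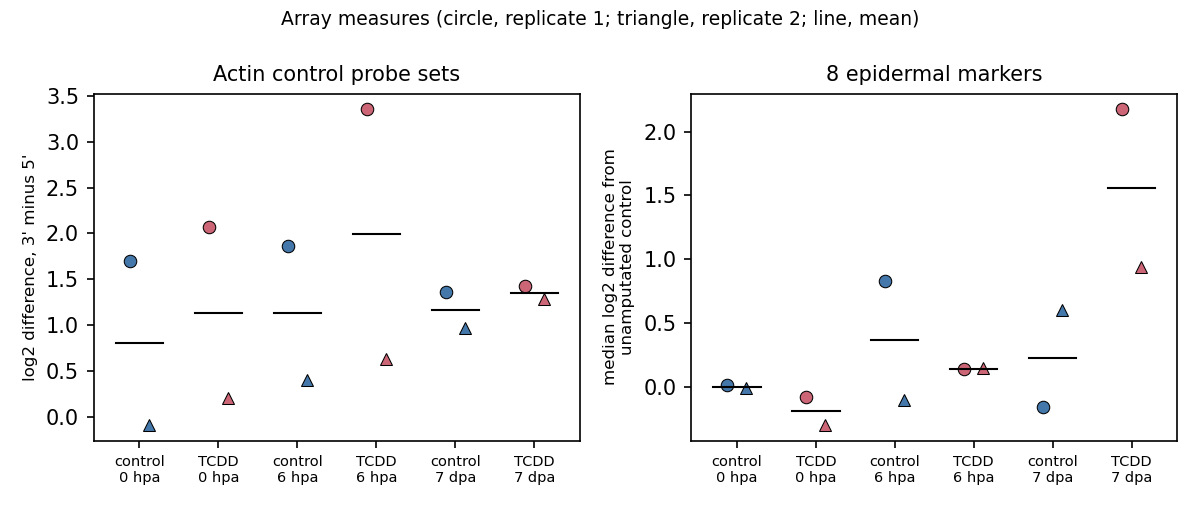
Difference in log2 intensity between the 3′ and 5′ actin control probe sets, and median log2 difference of 8 epidermal markers from the unamputated control mean, for each of the 12 arrays (circle, replicate 1; triangle, replicate 2). TCDD 6 hpa replicate 1 has the highest actin difference, 3.35, and the TCDD 7 dpa arrays the highest epidermal medians, 2.18 and 0.94.

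The first question was which genes the amputated control ventricle had turned on or off after 6 hours. Among the largest rises were those of 2 matrix-degrading enzymes: mmp9, a gelatinase, rose by 5.62 ± 0.80 log2 units (from 4.30 ± 0.39 to 9.92 ± 0.17, SD, n = 2 per group, adjusted p = 0.0299) and mmp13a, a collagenase, by 5.21 ± 0.85 (adjusted p = 0.0441). The phosphate transporter gene slc20a1a rose by 4.51 ± 0.53 and nt5dc2 by 3.84 ± 0.37 (both adjusted p = 0.0197). Among the falls were the genes of the type I collagen chains, col1a2 (−2.55 ± 0.32) and col1a1a (−2.44 ± 0.36). In all, 25 probe sets rose and 49 fell, of 1587 with an unadjusted p under 0.05. For the genes named here and below as the largest changes, both arrays of 1 group lay above both of the other.

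Other rises at 6 hpa in controls were tcimb (3.60 ± 0.46), znfl2a (3.30 ± 0.54), the kinase gene pim2 (3.09 ± 0.44), the purine salvage gene hprt1l (2.94 ± 0.45), igfbp1a, which encodes a binding protein of insulin-like growth factors (2.86 ± 0.46, adjusted p = 0.0441), and the water channel gene aqp1a.1 (2.49 ± 0.35). The largest fall was that of cfd, complement factor D, from 8.20 ± 0.58 to 4.60 ± 0.30 (−3.60 ± 0.40, adjusted p = 0.0197). It was followed by epas1b, a hypoxia-inducible factor (−3.39 ± 0.48), cdc42ep3 (−3.29 ± 0.47), the transferrin gene tfa (−2.39 ± 0.24), thbs3a, a thrombospondin (−2.35 ± 0.25), irx5a (−2.29 ± 0.38) and pcolcea, an enhancer of procollagen processing (−2.07 ± 0.34). The second probe sets of col1a2 (−1.60, adjusted p = 0.065) and col1a1a (−1.65, adjusted p = 0.24) did not pass.

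By list, 6 of 53 extracellular matrix genes fell and none rose, and 9 fell when adjusted over the list alone (camera adjusted p = 7.86e-06, and adjusted p = 0.229 with an estimated correlation). Among them decorin, dcn, fell by 1.86. Of 40 epicardial and fibroblast genes 2 fell, or 4 adjusted over the list alone (adjusted p = 0.000979, and 0.229 as adjusted p with an estimated correlation). Of 46 leukocyte genes 2 rose, also adjusted over the list alone: mmp9 and mmp13a, the matrix-degrading enzymes named above. In this list 37 genes had positive values (adjusted p = 4.49e-07, and adjusted p = 0.254 with an estimated correlation). The 91 genes of oxidative phosphorylation and the citric acid cycle had a median of −0.81 with 90 below 0, yet none passed singly over all probe sets or adjusted over the list alone; ndufv1 was at −1.14 ± 0.25 (adjusted p = 0.111). That list was called down at adjusted p = 1.97e-19, and adjusted p = 0.426 with an estimated correlation. Of 54 cardiomyocyte genes none passed over all probe sets, and 1 rose and 1 fell adjusted over the list alone (median −0.42, adjusted p = 9.89e-05, and adjusted p = 0.254 with an estimated correlation). Fatty acid metabolism had a median of −0.82 over 44 genes, 0 of them past the test, and 2 rises and 8 falls adjusted over the list alone (adjusted p = 0.000207, and adjusted p = 0.463 with an estimated correlation).

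The 37 erythrocyte genes had a median of 0.53, with 2 rises and 2 falls, and 15 rises and 3 falls adjusted over the list alone (adjusted p = 3.47e-07, and adjusted p = 0.229 with an estimated correlation). One of the falls was tfa, which encodes the iron carrier of plasma. Of 33 apoptosis genes casp9, an initiator caspase, rose by 1.70 ± 0.25, and 6 rose and 1 fell adjusted over the list alone (adjusted p = 0.00017, and adjusted p = 0.254 with an estimated correlation). Of 48 endothelial and endocardial genes 1 rose and 2 fell, erg among them (−1.52 ± 0.23), with 3 rises and 9 falls adjusted over the list alone (adjusted p = 0.0302, and adjusted p = 0.229 with an estimated correlation). Genes of ribosome biogenesis (median 0.16, adjusted p = 0.00127), the interferon response (0.11), the cell cycle (0.09), ribosomal proteins (0.05) and thrombocytes (0.12), each of the last 4 at adjusted p = 0.0419, tested up, and smooth muscle and valve genes down (−0.47, adjusted p = 0.0442). With an estimated correlation their adjusted p was 0.494, 0.787, 0.798, 0.802, 0.426 and 0.254. Not called were matrix proteases (2 rises of 21, or 4 rises and 4 falls adjusted over the list alone, adjusted p = 0.189), immediate early genes (1 rise of 77, or 4 rises and 2 falls adjusted over the list alone, adjusted p = 0.0706) and inflammation genes (1 fall of 52, or 2 rises and 3 falls adjusted over the list alone, adjusted p = 0.175). The proliferation marker pcna was at −0.05, fn1b at −0.74 and aldh1a2, which makes retinoic acid, at 1.46 ± 0.59 (adjusted p = 0.427).

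The count of 74 rested on single arrays. Without unamputated control replicate 1 or 2 it was 2 or 4, without control 6 hpa replicate 1 or 2 it was 2 or 19, and without TCDD 6 hpa replicate 1, which enters only through the shared spread, it was 309, including all 74. A fit of the 2 groups' arrays alone called 23. Some list calls rested on single arrays too. The cell cycle (adjusted p = 0.37), interferon (0.0872), thrombocyte (0.126) and ribosomal protein calls (0.108) were lost without unamputated control replicate 2. Those of smooth muscle (0.228) and ribosome biogenesis (0.0813) were lost without replicate 1. Interferon (0.316), endothelial (0.315), smooth muscle (0.0746) and ribosomal protein calls (0.201) were lost without control 6 hpa replicate 1, and cell cycle (0.546), thrombocyte (0.0973) and smooth muscle (0.0965) without replicate 2.

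At 7 dpa the question was which genes marked the control ventricle during regrowth. Lgals3bp.1, a galectin-3-binding protein gene, rose from 3.24 ± 0.03 to 9.48 ± 0.89 (SD, n = 2 per group, 6.24 ± 0.36, adjusted p = 0.00029), a size at best a lower bound, as the first level is not shown to be above background. Postnb, which encodes the matrix protein periostin, rose from 5.68 ± 0.46 to 10.14 ± 0.27 (4.46 ± 0.40, adjusted p = 0.0011), with a second probe set at 4.07. Of the muscle genes, ttn.2, a titin gene, fell by 3.32 (adjusted p = 0.0126, other probe sets at −2.78, −0.26 and −0.20) and ckmt2a, the mitochondrial creatine kinase, by 2.42 (adjusted p = 0.00984). Altogether 256 probe sets rose and 54 fell.

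The largest rises included further genes known from macrophages: marco, a scavenger receptor (4.38 ± 0.71), the granulin gene grna (4.29 ± 0.61), apoeb, an apolipoprotein E (4.20 ± 0.75), the cathepsin gene ctss2.1 (4.14 ± 0.68) and the complement gene c1qc (3.81 ± 0.58). Of 46 leukocyte genes 13 rose and none fell, or 28 adjusted over the list alone, and the median was 1.93 (adjusted p = 5.16e-17, and adjusted p = 0.0521 with an estimated correlation). Of 52 inflammation genes 5 rose, 14 adjusted over the list alone, with pycard, an inflammasome adaptor, at 2.75 ± 0.22 and cebpb at 2.68 ± 0.51 (adjusted p = 1.7e-12, and still called with adjusted p = 0.0311 with an estimated correlation). Of 25 interferon response genes 4 rose, among them isg15 (2.37 ± 0.45), gbp1 (2.08 ± 0.40) and psmb9a (1.78), and 9 rose adjusted over the list alone (adjusted p = 5.26e-08, and adjusted p = 0.274 with an estimated correlation).

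Among 53 extracellular matrix genes 13 rose and none fell, or 22 adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 3.4e-10 and 0.0311). The fibronectin gene fn1a rose by 4.13 ± 0.23 (adjusted p = 0.00029), while its other probe sets were at 0.39 and 0.24, and fn1b was at 1.99 ± 0.43 (adjusted p = 0.0592). Both type I collagen genes, which had fallen at 6 hpa, rose: col1a2 by 2.95 ± 0.32 and col1a1a by 2.90 ± 0.36. Of 21 matrix proteases and their inhibitors 5 rose, 8 adjusted over the list alone (adjusted p = 2.53e-06, and 0.0311 as adjusted p with an estimated correlation). They included the membrane-bound enzymes mmp14b (3.05 ± 0.28) and mmp14a (2.19 ± 0.23, second probe set 1.14), mmp2 (2.55 ± 0.30) and ctsk (2.60 ± 0.37), whereas mmp9 was at 0.96 ± 0.80 (adjusted p = 0.829). Of 40 epicardial and fibroblast genes 10 rose, 15 adjusted over the list alone (adjusted p = 9.46e-11, and 0.0307 as adjusted p with an estimated correlation). Clusterin, clu, rose by 4.08 ± 0.40, midkine, mdka, by 3.84 ± 0.26, the transglutaminase gene tgm2b by 2.95 ± 0.30 and the chemokine gene cxcl12a by 2.36 ± 0.34. The 112 growth factor and regeneration genes were not called (adjusted p = 0.135, median −0.01 and mean 0.19), though 7 rose, or 10 adjusted over the list alone.

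Of 96 cell cycle genes 11 rose and none fell, 24 rose adjusted over the list alone and 87 were above 0 (adjusted p = 6.58e-15, and adjusted p = 0.211 with an estimated correlation). Pcna, the clamp of DNA replication, rose from 5.85 ± 0.25 to 7.92 ± 0.50 (2.07 ± 0.29, adjusted p = 0.0104), kpna2, an importin, by 2.14 ± 0.22 and uhrf1, which maintains DNA methylation, by 1.68 ± 0.25, with a second uhrf1 probe set at 0.05. Of 72 ribosomal protein genes 68 were above 0 with a median of 0.30 and none past the test (adjusted p = 1.92e-08, and adjusted p = 0.514 with an estimated correlation). Immediate early genes gave 5 rises of 77, 7 adjusted over the list alone, with junbb at 2.83 ± 0.39 and zfp36l1a at 2.84 ± 0.48 (adjusted p = 0.00679, and adjusted p = 0.742 with an estimated correlation).

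Oxidative phosphorylation and citric acid cycle genes had a median of −1.02. Of 91, 3 fell, among them cyc1 (−1.56 ± 0.28) and ndufv2 (−1.52 ± 0.31), and 32 fell adjusted over the list alone (adjusted p = 3.39e-25, and adjusted p = 0.274 with an estimated correlation). Of 54 cardiomyocyte genes 3 fell, 11 adjusted over the list alone, casq2, the calcium store protein calsequestrin, by 1.63 (adjusted p = 1.93e-10, and adjusted p = 0.0521 with an estimated correlation). The fatty acid list had 1 fall of 44, acsl1a (−1.44 ± 0.25, other probe sets −1.84 to −0.59), 11 adjusted over the list alone, and a median of −0.93 (adjusted p = 7.4e-09, and adjusted p = 0.272 with an estimated correlation). Glycolysis and hypoxia genes gave 2 falls of 48, or 1 rise and 5 falls adjusted over the list alone (adjusted p = 0.000481, and adjusted p = 0.438 with an estimated correlation). Of 20 pancreas and gut genes 1 fell, ctrb.1, a chymotrypsinogen (−3.72 ± 0.75, adjusted p = 0.046). That list was called down at adjusted p = 0.00114, and adjusted p = 0.40 with an estimated correlation, and it was raised on unamputated control replicate 2, where ctrb.1 lay at 8.96.

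Of the other large falls, epas1b was at −2.76 ± 0.48, cep85 at −2.45 ± 0.38 with a second probe set at −1.23, spata20 at −2.34 ± 0.41, sall1a at −2.19 ± 0.41 and mapk4 at −2.19 ± 0.24. The 310 calls became 78 or 54 without unamputated control replicate 1 or 2, 179 without control 7 dpa replicate 1, and 627, including all 310, without TCDD 6 hpa replicate 1. With the epidermal level as a covariate there were 180, 162 of them among the 310; krt5 lay at 9.60 on control 7 dpa replicate 2 and at 2.67 on replicate 1. In this comparison and that of TCDD 7 dpa with 0 hpa, time coincides with any separate processing of the 7 dpa arrays, on all of which the DapX spike control was higher (5.67 or more) than on the others (3.99 or less). The pancreas and gut list was not called without unamputated control replicate 2 (adjusted p = 0.144) or control 7 dpa replicate 1 (0.0607), immediate early genes not without the latter (0.116), and glycolysis genes not without control 7 dpa replicate 2 (0.181).

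In TCDD-treated fish the same questions were asked against the unamputated TCDD group. At 6 hpa slc20a1a rose by 5.20 ± 0.53 (adjusted p = 0.00984), igfbp1a by 5.05 ± 0.46 and nt5dc2 by 4.38 ± 0.37 (both adjusted p = 0.00746). Mmp9 rose from 4.75 ± 0.57 to 9.0 ± 2.0 (SD, n = 2 per group, adjusted p = 0.0398). Among the falls were acads, an enzyme of fatty acid oxidation (−2.41 ± 0.45), col1a1a (−2.39 ± 0.36, second probe set −1.05) and the cardiac transcription factor gene gata5 (−2.21 ± 0.35). The counts were 72 rises and 219 falls, but 63 rises and 38 falls without TCDD 6 hpa replicate 1. The median of all probe sets was 0.06, or −0.09 after centring each array on its median.

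Further rises at 6 hpa under TCDD were tcimb (4.02 ± 0.46), mibp (3.77 ± 0.41), pim2 (3.67 ± 0.44) and znfl2a (3.49 ± 0.54). Of 37 erythrocyte genes 11 rose and 3 fell, or 18 and 3 adjusted over the list alone. They included epb41b, a membrane skeleton protein (3.23 ± 0.46), the anion exchanger gene slc4a1a (3.18 ± 0.59) and the blood transcription factor genes klf1 (2.97 ± 0.55) and tal1 (2.94 ± 0.50). The list was called up at adjusted p = 6.42e-07, and adjusted p = 0.369 with an estimated correlation, with a median of 0.63, and 1 gene rose and 1 fell in it without TCDD 6 hpa replicate 1. Of 33 apoptosis genes 1 rose and 1 fell, 7 and 1 adjusted over the list alone (adjusted p = 0.0249, and adjusted p = 0.692 with an estimated correlation).

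Of 91 oxidative phosphorylation genes 7 fell, ndufv1 by 1.77 and ndufs1 by 1.82 among them, and 80 fell and 1 rose adjusted over the list alone. The list's median was −1.31, or −0.63 without TCDD 6 hpa replicate 1, the array with the actin difference of 3.35 (adjusted p = 9.86e-29, and adjusted p = 0.404 with an estimated correlation). Of 44 fatty acid genes 4 fell, 23 adjusted over the list alone, etfdh by 2.35 (adjusted p = 7.48e-08, and adjusted p = 0.404 with an estimated correlation). Of 54 cardiomyocyte genes 5 fell, or 1 rose and 21 fell adjusted over the list alone, with nexn, a protein of the sarcomere, at −2.31 ± 0.44 and tbx5a at −1.71 ± 0.32, its second probe set at −0.38 (adjusted p = 7.48e-08, and adjusted p = 0.369 with an estimated correlation). Of 48 glycolysis and hypoxia genes 1 rose and 4 fell, such as tpi1a, triosephosphate isomerase (−1.50 ± 0.21), with 4 rises and 16 falls adjusted over the list alone (adjusted p = 0.0208, and adjusted p = 0.692 with an estimated correlation). Of 40 epicardial and fibroblast genes 4 fell, 11 adjusted over the list alone (adjusted p = 0.012, and adjusted p = 0.369 with an estimated correlation). With TCDD 6 hpa replicate 1 left out the falls were 1 for oxidative phosphorylation, 0 for fatty acid genes (median −0.73, from −1.37), 0 for cardiomyocyte genes (−0.38, from −0.75), 0 for glycolysis genes (−0.12, from −0.48, with 2 rises and the list no longer called at adjusted p = 0.193) and 2 for epicardial genes. The largest single falls were tmem178a (−3.39 ± 0.53), cdc42ep3 (−3.17 ± 0.47), palm1b (−2.95 ± 0.50), krt94 (−2.77 ± 0.48), cd248a (−2.72 ± 0.49), the retinol carrier gene rbp4 (−2.72 ± 0.56), crip2 (−2.64 ± 0.54) and sesn3 (−2.63 ± 0.35).

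Cell cycle genes (median 0.16, adjusted p = 0.000995) and hepatocyte genes (0.19, adjusted p = 0.0351) tested up, and heat shock genes down (−0.39, adjusted p = 0.0293). With an estimated correlation their adjusted p was 0.692, 0.763 and 0.692. Leaving out TCDD 6 hpa replicate 1 gave medians of 0.04, 0.04 and −0.13, and none of these calls held (adjusted p = 0.193, 0.819 and 0.48). The hepatocyte call was lost without TCDD 0 hpa replicate 2 (adjusted p = 0.237), the heat shock (0.119), glycolysis (0.0732) and apoptosis calls (0.0792) without replicate 1, and the epicardial (0.0596) and apoptosis calls (0.317) without TCDD 6 hpa replicate 2. In the hepatocyte list the 2 genes that passed, rbp4 and tfa, both fell. The 53 matrix genes gave 5 falls, 6 adjusted over the list alone, and were not called as a list (adjusted p = 0.158). The 291 calls depended on the arrays of both groups. Without TCDD 0 hpa replicate 1 or 2 limma called 0, without TCDD 6 hpa replicate 2 it called 2424, and without TCDD 6 hpa replicate 1 it called 101, 62 of them among the 291. A fit of the 2 groups' arrays alone called 0, where all arrays together gave 2659 at an unadjusted p under 0.05.

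At 7 dpa under TCDD the comparison asked the same of the later stage. The apolipoprotein gene apoeb rose by 6.44 ± 0.75 (adjusted p = 0.00314) and postnb from 5.08 ± 0.04 to 9.71 ± 0.53 (4.64 ± 0.40, SD, n = 2 per group, adjusted p = 0.000727). Ca2, a carbonic anhydrase, rose from 2.64 ± 0.08 to 8.92 ± 0.39 (6.28 ± 0.22, adjusted p = 7.31e-06), though its second probe set was at 0.61. The keratin genes krt97 (6.06 ± 1.19), krt91 (5.84 ± 0.69), krt17 (5.72 ± 0.87) and krt4 (3.95 ± 0.42) and the aquaglyceroporin gene aqp3a (6.31 ± 0.52) rose on the arrays whose epidermal medians were 2.18 and 0.94. In all 305 probe sets rose and 62 fell.

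Of 53 matrix genes 14 rose and none fell, or 22 adjusted over the list alone, fn1a by 4.35 ± 0.23 (other probe sets 0.08 and −0.45), col1a2 by 2.86 ± 0.32 and fn1b by 2.82 ± 0.43 (adjusted p = 5.83e-10, and 0.0369 as adjusted p with an estimated correlation). Of 21 matrix proteases and inhibitors 6 rose, 11 adjusted over the list alone, among them mmp14b (2.62 ± 0.28), mmp2 (2.53 ± 0.30) and timp2b, an inhibitor of these enzymes (4.70 ± 0.80), while mmp9 was at 3.33 ± 0.80 (adjusted p = 0.0773). The protease list was called at adjusted p = 1.5e-08, and adjusted p = 0.0369 with an estimated correlation. Of 40 epicardial and fibroblast genes 11 rose, 15 adjusted over the list alone (adjusted p = 7.28e-08, and 0.0369 as adjusted p with an estimated correlation). That list holds krt4 and krt15, keratins that epidermis expresses too. Midkine rose by 3.96 ± 0.26, clusterin by 3.81 ± 0.40 and crabp2a, which binds retinoic acid, by 3.21 ± 0.27.

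Leukocyte genes gave 5 rises of 46, 12 adjusted over the list alone, and a median of 1.03 (adjusted p = 2.73e-09, and adjusted p = 0.175 with an estimated correlation). Inflammation genes gave 6 rises of 52, 9 adjusted over the list alone, pycard by 3.80 ± 0.22 and anxa1b, an annexin, by 4.06 ± 0.39 (adjusted p = 4.75e-08, and adjusted p = 0.092 with an estimated correlation). Of 25 interferon genes isg15 alone rose, by 2.72 ± 0.45, also adjusted over the list alone (adjusted p = 0.00117, and adjusted p = 0.646 with an estimated correlation). Of 96 cell cycle genes 4 rose, 11 adjusted over the list alone, cdk1 by 1.08 ± 0.20 and kpna2 by 1.56 ± 0.22, and pcna was at 1.30 ± 0.29 (adjusted p = 0.0603). The cell cycle list was called at adjusted p = 1.34e-05, and adjusted p = 0.607 with an estimated correlation.

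Among muscle and metabolic genes under TCDD at 7 dpa, 3 of 54 cardiomyocyte genes fell, 7 adjusted over the list alone. Ttn.2 fell by 2.96 (other probe sets −2.04, −0.22 and −0.17), ckmt2a by 2.55 and casq2 by 1.42 (adjusted p = 2.52e-07, and adjusted p = 0.143 with an estimated correlation). The median of 91 oxidative phosphorylation genes was −0.92, with 0 falls over all probe sets by limma and 24 adjusted over the list alone (adjusted p = 2.96e-22, and adjusted p = 0.412 with an estimated correlation). Fatty acid genes had a median of −1.07 over 44 genes and 3 falls adjusted over the list alone (adjusted p = 9.04e-08, and adjusted p = 0.378 with an estimated correlation). Of 48 glycolysis and hypoxia genes 2 fell, eno3, an enolase, by 1.43 and tpi1a by 1.16, and 1 rose and 6 fell adjusted over the list alone (adjusted p = 0.0479, and adjusted p = 0.784 with an estimated correlation). The largest fall was that of rbp2a, a retinol-binding protein gene (−3.06 ± 0.58). The 367 calls became 115 or 101 without TCDD 0 hpa replicate 1 or 2, 153 or 218 without TCDD 7 dpa replicate 1 or 2, 683 without TCDD 6 hpa replicate 1, and 2 with the epidermal level as a covariate. The interferon (adjusted p = 0.403) and glycolysis calls (0.171) were lost without TCDD 0 hpa replicate 1, and the latter also without TCDD 7 dpa replicate 1 (0.0554).

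**Figure D2:**
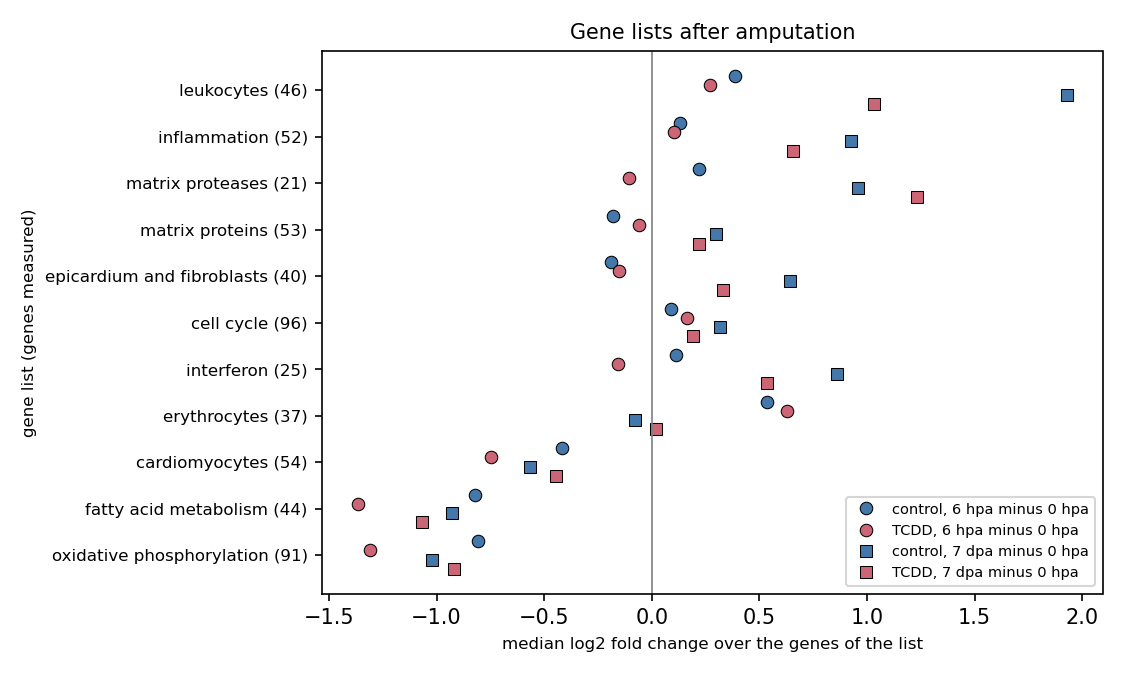
Median log2 fold change of 11 gene lists in the 4 comparisons of an amputated group with the unamputated group of the same treatment; each point is 1 list in 1 comparison. The oxidative phosphorylation list lies at −0.81 and −1.02 in controls and at −1.31 and −0.92 under TCDD, and the leukocyte list reaches 1.93 in controls and 1.03 under TCDD at 7 dpa.

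The amputation responses of both treatments were then set side by side; they share no array. Across probe sets, which are not independent replicates, the log2 fold changes of control and TCDD fish correlated at r = 0.79 at 6 hpa and r = 0.78 at 7 dpa. At 6 hpa 21 probe sets rose in both and 33 fell in both, where independent lists would share 0.116 and 0.692. At 7 dpa 147 rose in both and 24 fell in both, against 5.04 and 0.216. Both comparisons use 1 estimate of the spread for each probe set, so their lists are not independent even without shared arrays. At 7 dpa both also rest on the arrays with the higher DapX spike control. Of the 74 called in controls at 6 hpa 73 had the same sign under TCDD, and 305 of 310 at 7 dpa, and 0 were called in opposite directions. Among the shared genes are slc20a1a, mmp9 and pim2 early, and postnb, fn1a, mdka and clu at 7 dpa.

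The next question was what TCDD did before any injury. In unamputated ventricles cyp1a, the monooxygenase gene that AHR induces, rose from 3.56 ± 0.11 to 11.89 ± 0.20 (SD, n = 2 per group, 8.33 ± 0.47, adjusted p = 0.000514). The control level lies near the median of the arrays (3.26 to 3.53) and is not shown to be above background, so the size is at best a lower bound. Cxxc5a, a zinc finger gene, rose by 2.88 ± 0.24 (adjusted p = 0.00784), and cdo1, cysteine dioxygenase, fell from 8.88 ± 0.15 to 6.64 ± 0.43 (−2.24 ± 0.25, adjusted p = 0.0434). In total 3 probe sets rose and 1 fell, of 225 with an unadjusted p under 0.05. The AHR target cyp1c1 was at 4.30 ± 0.90 (adjusted p = 0.849, other probe sets 0.12 and 1.14), the receptor gene ahr2 at 1.12 ± 0.52 and edn1, endothelin, at 2.66 ± 0.49 (adjusted p = 0.587).

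Of 18 genes of the AHR battery 1 rose, cyp1a, or 3 adjusted over the list alone. The median was 0.02 and the mean 0.94, with 9 genes above 0 and 9 below (adjusted p = 6.3e-06, and adjusted p = 0.0717 with an estimated correlation). In the other lists no gene passed over all probe sets, while 1 endothelial gene rose and 1 heat shock gene fell adjusted over the list alone. In the matrix protease list, which was not called (camera adjusted p = 0.65), mmp2 was at −1.03 ± 0.30. Extracellular matrix genes had a median of −0.18 with 40 of 53 below 0 (adjusted p = 8.67e-07, and adjusted p = 0.122 with an estimated correlation). Thbs3a at −0.84 ± 0.25 and lamb1a at −0.90 ± 0.31 are examples. Epicardial and fibroblast genes (−0.08, adjusted p = 0.000439), smooth muscle and valve genes (−0.22, adjusted p = 0.00285), endothelial genes (−0.12, adjusted p = 0.0293), erythrocyte genes (−0.16, adjusted p = 0.0013) and pancreas and gut genes (−0.37, adjusted p = 8.03e-06) tested down too. With an estimated correlation the adjusted p was 0.122 for epicardial and smooth muscle genes, 0.161 for endothelial, 0.483 for erythrocyte and 0.329 for pancreas and gut genes. Interferon genes (0.37, adjusted p = 3.26e-05) and leukocyte genes (0.10, adjusted p = 0.0217) tested up, with adjusted p = 0.608 and adjusted p = 0.805 with an estimated correlation. The leukocyte list holds mpx by a probe set at 3.16 ± 0.66 in the mean TCDD effect over the 3 times. The other mpx probe sets were at 0.00, 0.03 and 0.10, and whether the first measures mpx was not tested. Most of these list calls rested on single arrays. The pancreas and gut call was lost without control replicate 2, the array with raised pancreas genes (adjusted p = 0.459), and the interferon call without TCDD replicate 2 (0.795), where that list lay at 0.288 against −0.443 on replicate 1. The leukocyte call was lost without control replicate 1 (0.172) or 2 (0.0554) or TCDD replicate 2 (0.583), and the endothelial call without the same arrays (0.0786, 0.136 and 0.242). The erythrocyte call was lost without control or TCDD replicate 2 (0.0676 and 0.0525). The epicardial call was lost without control replicate 1 (0.172) or TCDD replicate 2 (0.0627), and the smooth muscle call without control replicate 1 (0.225). The 4 calls of single probe sets became 2 without control replicate 1 and 1 without control replicate 2, TCDD replicate 1 or TCDD replicate 2, and cdo1 did not pass without TCDD 6 hpa replicate 1 (adjusted p = 0.0624).

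At 6 hpa the comparison asked how TCDD changed the early response. Cyp1a rose from 2.89 ± 0.25 to 10.24 ± 1.21 (7.35 ± 0.47, SD, n = 2 per group, adjusted p = 0.00116), and dnase1l4.1, a DNase I-like gene, rose from 2.98 ± 0.13 to 5.71 ± 0.06 (2.73 ± 0.18, adjusted p = 0.00116). These were the 2 calls, of 421 probe sets with an unadjusted p under 0.05, and 0 fell by limma. Cyp1c1 was at 2.90 ± 0.90 (other probe sets 0.38 and 0.01), mmp9 at −0.92 ± 0.80, fn1b at −1.56 ± 0.43 and aldh1a2 at −1.60 ± 0.59, each at an adjusted p of 1. Without TCDD 6 hpa replicate 1 these values were 4.22, 0.50, −0.73 and −0.76, while cyp1a was at 8.21 and dnase1l4.1 at 2.69.

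Several lists tested down at 6 hpa, and most of their medians shrank without that array. Oxidative phosphorylation genes had a median of −0.54 with 89 of 91 below 0 (adjusted p = 2.86e-20, and adjusted p = 0.462 with an estimated correlation), but 0.10 without TCDD 6 hpa replicate 1. Fatty acid genes went from −0.66 (adjusted p = 1e-07) to −0.12, cardiomyocyte genes from −0.37 (adjusted p = 2.01e-08) to −0.18, glycolysis genes from −0.36 to −0.11 and heat shock genes from −0.28 to −0.06 (both adjusted p = 1.6e-05). For cardiomyocyte genes this was adjusted p = 0.226 with an estimated correlation, and for the other 3 lists adjusted p = 0.462. Immediate early genes went from −0.26 (adjusted p = 0.00712) to 0.18 and leukocyte genes from −0.42 (adjusted p = 0.0277) to 0.06, with adjusted p = 0.826 and adjusted p = 0.811 with an estimated correlation. Ribosome biogenesis (−0.16, adjusted p = 0.00152) and epicardial genes (−0.10, adjusted p = 0.00577) tested down, and cell cycle genes up (0.10, adjusted p = 0.00531), with medians of 0.00, −0.08 and −0.04 without that array. These had adjusted p = 0.686, 0.329 and 0.826 with an estimated correlation. Leaving out TCDD 6 hpa replicate 1 ended the calls of ribosome biogenesis (adjusted p = 0.708), cell cycle (0.296), leukocyte (0.298), glycolysis (0.213), heat shock (0.203), fatty acid (0.146) and oxidative phosphorylation genes (0.125) and turned that of immediate early genes (0.000305). Without control 6 hpa replicate 2 the leukocyte (0.751), immediate early (0.221) and epicardial calls (0.197) were lost, without replicate 1 the cell cycle call (0.423), and without TCDD 6 hpa replicate 2 the AHR (0.156) and epicardial calls (0.125). Of the 18 AHR genes cyp1a rose, or 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.00152, and adjusted p = 0.226 with an estimated correlation). The median was 0.30, or 0.05 without TCDD 6 hpa replicate 1. No member of another list passed. Examples are stat3 at −1.28 ± 0.33 and nexn at −1.65 ± 0.44, or −0.84 and −1.11 without TCDD 6 hpa replicate 1. Without TCDD 6 hpa replicate 2 limma called 762 probe sets, and in a fit of the 2 groups' arrays alone 0.

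The comparison at 7 dpa asked which genes TCDD had changed in the regenerating ventricle. Cyp1a rose from 2.96 ± 0.00 to 11.83 ± 0.50 (8.87 ± 0.47, SD, n = 2 per group) and ca2 from 4.78 ± 0.18 to 8.92 ± 0.39 (4.14 ± 0.22, both adjusted p = 0.00015); the second ca2 probe set was at 0.68. Further rises were those of ccl27a, a chemokine (4.03 ± 0.42, adjusted p = 0.0208), icn2, an S100-type protein (3.98 ± 0.51, adjusted p = 0.0386), anxa1b (3.42 ± 0.39, adjusted p = 0.0261), cd44a, a hyaluronan receptor (3.05 ± 0.40) and plaua, urokinase (2.2 ± 0.25). Cxcl12a, a chemokine gene that had risen in regenerating controls, was lower under TCDD by both of its probe sets (−2.58 ± 0.34 and −2.25, adjusted p = 0.0386 and 0.0208), as was f13a1b, a clotting factor XIII subunit (−1.45 ± 0.19, adjusted p = 0.04), though its other probe sets, at −2.25 (adjusted p = 0.167) and −0.19, did not pass. The counts were 12 rises and 6 falls, of 615 probe sets with an unadjusted p under 0.05.

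Mid1ip1a, a regulator of lipid synthesis (2.30 ± 0.30), crabp2a (2.28 ± 0.27) and cxxc5a (1.99 ± 0.24), which had also risen before injury and was named after its values were seen, rose as well. Of 52 inflammation genes 2 rose, icn2 and anxa1b, and 1 fell, or 5 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.737). Both also serve as epidermal markers, and on control 7 dpa replicate 2 anxa1b was higher than on replicate 1 by 1.53 and icn2, by its second probe set (3.94, adjusted p = 0.033), by 1.88. Of 21 matrix proteases 1 rose, plaua, or 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.0969), with mmp9 at 2.83 ± 0.80 (adjusted p = 0.559, from 5.26 ± 1.00 to 8.09 ± 0.19). Of 18 AHR genes cyp1a rose, 4 adjusted over the list alone, and 13 were above 0 (adjusted p = 3.42e-06, and adjusted p = 0.069 with an estimated correlation). Of other epidermal genes that did not pass singly, the first 4 picked after their values had been seen, krt5 was at 4.41, krt97 at 4.08, krt17 at 4.01, epcam at 3.61 and cldnb at 3.26 (adjusted p = 0.194 for cldnb), while gsdmeb was at −0.35, abcb5 at −0.12 and cldnd at −0.10. Krt5 lay at 10.62 and 10.47 on the TCDD arrays, at 9.60 on control 7 dpa replicate 2 and at 2.67 on replicate 1.

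Cell cycle genes tested lower under TCDD at 7 dpa. The median was −0.17 with 75 of 96 below 0, no gene passed over all probe sets and 1 fell adjusted over the list alone (adjusted p = 1.48e-08, and adjusted p = 0.472 with an estimated correlation). Mcm5, a replication helicase gene, was at −1.04 ± 0.18 (adjusted p = 0.122) and pcna at −0.68 ± 0.29. Ribosomal protein genes had a median of −0.22 with 70 of 72 below 0 and none past the test (adjusted p = 1.12e-09, and adjusted p = 0.625 with an estimated correlation). Leukocyte genes (−0.35, adjusted p = 0.00556), matrix genes (−0.10, adjusted p = 0.00361), epicardial genes (−0.14, adjusted p = 0.00361) and endothelial genes (−0.13, adjusted p = 0.031) tested down, with adjusted p = 0.625, 0.398, 0.243 and 0.243 with an estimated correlation. The epicardial list held 1 fall, 2 adjusted over the list alone, and the matrix list 1 rise and 2 falls adjusted over the list alone. Loxa, which crosslinks collagen, was at −1.0 ± 0.18 (adjusted p = 0.122) and plvapb, an endothelial gene, at −1.60 ± 0.41 (adjusted p = 0.383). Oxidative phosphorylation and cardiomyocyte genes were not called as lists (medians 0.00 and −0.01, adjusted p = 0.937 and 0.723), nor did fn1b (−0.01) or aldh1a2 (0.10) pass. The 18 calls became 11 without control replicate 1, 6 of them among the 18. Without control replicate 2, where krt5 was high, there were 98, with 16 of the 18. Without TCDD replicate 1 there were 6, with cyp1a, ca2, ccl27a and plaua left of the 18. Without TCDD replicate 2 there were 20, with 6 of the 18. Without TCDD 6 hpa replicate 1 there were 27, including all 18, while a fit of the 2 groups' arrays alone called 2, and so did one with the epidermal level as a covariate. The cell cycle (adjusted p = 0.0655), matrix (0.191) and epicardial calls (0.125) were lost without control replicate 2, and the leukocyte (0.596) and endothelial calls (0.198) without control replicate 1. The endothelial call was also lost without TCDD replicate 1 (0.168), and the matrix call (0.0959) and the epicardial, endothelial and leukocyte calls (each 0.0618) without TCDD replicate 2.

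**Figure D3:**
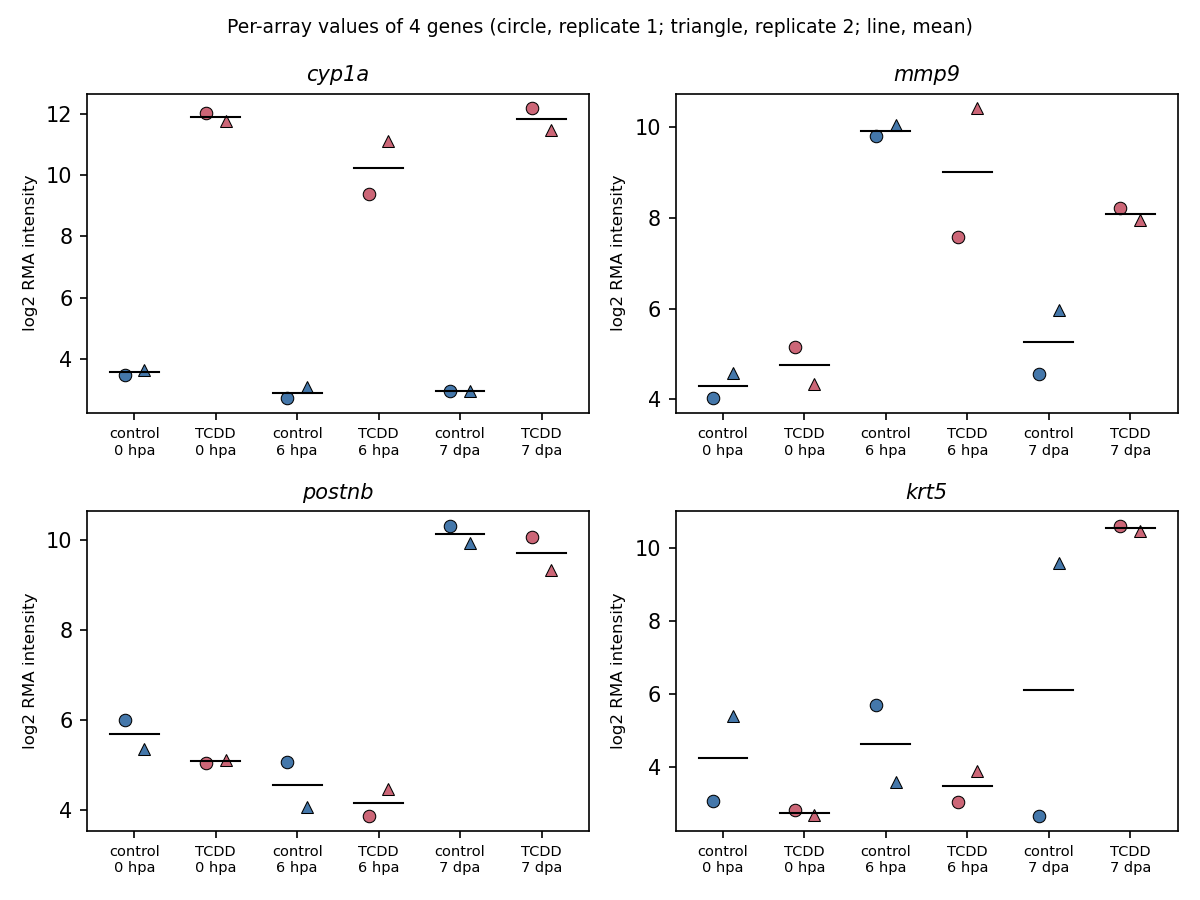
Log2 RMA intensity of cyp1a, mmp9, postnb and krt5 on each of the 12 arrays by group (circle, replicate 1; triangle, replicate 2; line, mean of the group). Cyp1a rises from 2.96 to 11.83 in the means of the 7 dpa groups, postnb is high in both treatments at 7 dpa (10.14 and 9.71), and krt5 is at 9.60 on 1 control 7 dpa array and at 2.67 on the other.

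Averaged over the 3 times, TCDD raised cyp1a by 8.18 ± 0.27 (adjusted p = 4.99e-06), tiparp, another AHR target, by 2.05 ± 0.25 (adjusted p = 0.0435), notum1b, which inactivates Wnt ligands, by 1.40 ± 0.16 (adjusted p = 0.0332) and ca2 by 1.31 ± 0.13 (adjusted p = 0.00931, second probe set 0.26). The value for ca2 comes from 7 dpa, with −0.05 at 0 hpa, −0.16 at 6 hpa and 4.14 at 7 dpa. On average cdo1 fell by 1.59 ± 0.15 (adjusted p = 0.00802), with −2.24, −1.81 and −0.72 at the 3 times. These belong to 7 probe sets that rose and 1 that fell, of 452 with an unadjusted p under 0.05. Cyp1c1 was at 3.47 ± 0.52 (adjusted p = 0.126, other probe sets 0.13 and 0.62), and at 3.91 with an adjusted p of 0.0157 without TCDD 6 hpa replicate 1. Ahr2 was at 0.85 ± 0.30, and nqo1, a quinone reductase gene, at 1.03 ± 0.34.

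Of the AHR list 2 of 18 rose, 5 adjusted over the list alone, and the call held with an estimated correlation (adjusted p = 1.59e-07 and 0.0384; median 0.07, mean 0.91). Epicardial and fibroblast genes were the other list whose camera call held (adjusted p = 3.3e-07, and 0.0423 as adjusted p with an estimated correlation). By fry the AHR list was called (adjusted p = 0.00416) and the epicardial list was not (adjusted p = 0.0585). The epicardial median was −0.12 with 30 of 40 below 0. No epicardial gene passed over all probe sets and 5 fell adjusted over the list alone. Smooth muscle and valve genes had 10 of 11 below 0 (−0.26, adjusted p = 0.000741), endothelial genes a median of −0.10 (adjusted p = 0.000893) and matrix genes one of −0.12 (adjusted p = 0.000136), with adjusted p = 0.08, 0.0664 and 0.158 with an estimated correlation. Pcolcea, of the collagen pathway, was at −0.94 ± 0.19 (adjusted p = 0.435). Oxidative phosphorylation (−0.22, adjusted p = 2.86e-09), fatty acid (−0.20, adjusted p = 0.00082) and glycolysis genes (−0.13, adjusted p = 0.0065) tested down with medians of 0.03, −0.01 and −0.02 without TCDD 6 hpa replicate 1 (adjusted p = 0.844, 0.394 and 0.551). For each of the 3 it was adjusted p = 0.714 with an estimated correlation. Ribosomal protein genes (−0.10, adjusted p = 4.65e-06) and cardiomyocyte genes (−0.12, adjusted p = 0.000121) tested down as well, with adjusted p = 0.714 and adjusted p = 0.274 with an estimated correlation. Without TCDD 6 hpa replicate 1 the ribosomal protein median was −0.03 and the call lost (adjusted p = 0.185), and the smooth muscle and endothelial medians were −0.16 and −0.06. The matrix call was lost without TCDD 6 hpa replicate 2 (adjusted p = 0.176), the fatty acid call without TCDD 7 dpa replicate 2 (0.168) or control 7 dpa replicate 1 (0.127), and the glycolysis call without the latter (0.295) or control 6 hpa replicate 1 (0.0539).

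The 8 calls ranged with the array left out. They were 5 or 4 without control 6 hpa replicate 1 or 2, 26 without control 7 dpa replicate 2, 4 without either TCDD 0 hpa array, and 14 or 41 without TCDD 6 hpa replicate 1 or 2. With the epidermal level as a covariate there were 3. Across probe sets the TCDD effects at different times correlated weakly, at r = 0.17 between 0 and 6 hpa, 0.21 between 0 hpa and 7 dpa and −0.02 between 6 hpa and 7 dpa. With TCDD 6 hpa replicate 1 left out the correlations with 6 hpa were 0.306 and 0.117.

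Whether TCDD changed the response to amputation itself was tested by the interactions. At 6 hpa dnase1l4.1 alone passed, with a response larger by 3.39 ± 0.26 log2 units under TCDD than in controls (adjusted p = 0.00699), and at 7 dpa ca2 alone, with a response larger by 4.19 ± 0.31 (adjusted p = 0.0049). The second ca2 probe set was at 0.74. Ca2 rose after amputation in controls as well, by 2.09 ± 0.22, with the second probe set at −0.13. No interaction passed for mmp9, pcna, postnb or the keratin genes, and 176 and 311 probe sets had an unadjusted p under 0.05. The igfbp1a response at 6 hpa differed by 2.19 ± 0.65 (adjusted p = 1).

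By list, the 6 hpa interaction was called for 13 lists with the preset correlation and for 0 with an estimated one (camera, adjusted p = 0.655 for all). The median difference in response was −0.66 for leukocyte genes (adjusted p = 0.000579), −0.22 for immediate early genes (adjusted p = 0.00576) and −0.49 for oxidative phosphorylation genes (adjusted p = 4.3e-12), whose fall was larger under TCDD, each with adjusted p = 0.655 with an estimated correlation. Without TCDD 6 hpa replicate 1 these medians were −0.06, 0.12 and 0.16, with the leukocyte call lost (adjusted p = 0.478) and the others in the opposite direction (0.0295 and 0.0144). Without control 6 hpa replicate 2 the leukocyte (0.473) and immediate early calls (0.133) were lost as well, the latter also without TCDD 0 hpa replicate 2 (0.656). Of the 13 calls only that of pancreas and gut genes (0.56, or 0.43 without this array, and adjusted p = 0.655 with an estimated correlation) kept both its direction and its side of the threshold, and it was lost without control 0 hpa replicate 2 (adjusted p = 0.0911). At 7 dpa 4 lists were called: cell cycle (−0.20, adjusted p = 4.95e-06), ribosomal protein (−0.17, adjusted p = 3.27e-05), leukocyte (−0.64, adjusted p = 9e-05) and interferon genes (−0.24, adjusted p = 0.00443), each with adjusted p = 0.963 with an estimated correlation. The cell cycle call was lost without control 7 dpa replicate 2 (adjusted p = 0.205), the leukocyte call without replicate 1 (0.106) and the ribosomal protein call without TCDD 7 dpa replicate 1 (0.164). The interferon call was lost without TCDD 0 hpa replicate 2 (0.818), TCDD 7 dpa replicate 2 (0.13) or control 7 dpa replicate 1 (0.218). Without control 6 hpa or TCDD 0 hpa arrays, each left out singly, limma called 0 in the 6 hpa interaction, without control 0 hpa replicate 1 it called 2, and without TCDD 6 hpa replicate 2 it called 120. At 7 dpa limma called 0 without any of the arrays at 0 hpa, 6 or 31 without control 7 dpa replicate 1 or 2, and 3 or 5 without TCDD 7 dpa replicate 1 or 2, and 0 with the epidermal level as a covariate.

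The lists of growth factor and regeneration, circadian clock, cholesterol synthesis and Nrf2 oxidative stress genes were called in none of the 10 comparisons. Their smallest adjusted p was 0.127 at the 6 hpa interaction, 0.117 in control 6 hpa, 0.114 in control 7 dpa and 0.236 in unamputated TCDD ventricles.

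In the authors' deposited table for unamputated control, 2025 features have an adjusted p under 0.05 and 0 of them a positive score, and in the authors' deposited table for TCDD 6 hpa 886, again with 0 positive scores. The authors' deposited tables for control 6 hpa, control 7 dpa and TCDD 7 dpa hold 0 such features in GenePattern's permutation test, with smallest adjusted p-values of 0.0648, 0.0901 and 0.0708. In the authors' deposited table for TCDD 7 dpa, cyp1a has a score of 4.93, a fold of 9.82 and an adjusted p of 0.518, and in the authors' deposited table for TCDD 6 hpa a score of 1.6, a fold of 136 and an adjusted p of 0.904. Both 6 hpa tables write their class with a 7 in the header, but their class means correlate at r = 0.995 with the control 6 hpa and r = 0.994 with the TCDD 6 hpa means, against r = 0.91 and r = 0.882 with the 7 dpa means of the same treatment.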

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

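The tests of RNA quality and of a shared TCDD response on TCDD 6 hpa replicate 1 and the count of other splits of the arrays were chosen after their results, or an earlier form of them, had been seen; the epidermal and intensity scale tests were set before.

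The interaction of dnase1l4.1 at 6 hpa stood out because its amputation response differed between treatments, by 3.39 ± 0.26 log2 units (adjusted p = 0.00699). That of ca2 at 7 dpa differed by 4.19 ± 0.31 (adjusted p = 0.0049), on 1 of its 2 probe sets. Among control probe sets outside the comparisons, 2 of the array's own control probe sets, which are named only by sequence accessions in the tables used here, lay at 8.55 and 10.04 on control 0 hpa replicate 2 and at or below 2.85 and 2.75 on the other 11 arrays. The DapX spike control lay at 5.67 or more on all 4 arrays at 7 dpa and between 2.97 and 3.99 on the other 8. Whether those 4 arrays were processed apart is not stated in the sources used here, and such a difference would coincide with time in the 310 and 367 calls of 7 dpa against 0 hpa.

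Genes higher under TCDD than in controls at 7 dpa came with epidermal genes. Over the 8 epidermal markers above log2 5 on some array, of 32 whose values had not been looked at, the median TCDD minus control difference was 1.21 with 7 above 0. Over all 32 it was 0.39 with 27 above 0. The limit used all 12 arrays, so it favours markers that are high on the TCDD 7 dpa arrays. Ppl passed it only on TCDD 7 dpa replicate 1 (5.22). Of the 8 markers, 1 lay above log2 5 in both unamputated control pools and 0 are in a tested list. Of the 12 probe sets that rose, 9 were also higher on control 7 dpa replicate 2 than on replicate 1. The share over all probe sets was not counted, and replicate 2 had the higher array median (3.38 against 3.28). This count alone therefore does not point to epidermis. Epidermal cells in the pooled pieces may account for part of the list, a hypothesis from the same data. TCDD as the only cause stays open, because the same markers lay 0.606 above the unamputated control mean on control 7 dpa replicate 2, between the 0.5 and the 1 set beforehand to decide it, and −0.16 from it on replicate 1. An epidermal covariate, which overlaps with the TCDD 7 dpa group, left 2 of the 18 calls for TCDD at 7 dpa, cyp1a and ca2 (8.95 ± 0.80 and 3.73 ± 0.33, both adjusted p = 0.0314).

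TCDD 6 hpa replicate 1 stood apart from all other arrays. A compressed intensity scale is argued against, since the probe sets lying more than 1 log2 unit beyond all other arrays were 663 before quantile normalization and 664 after it, or 100.2%. A TCDD response shared by both pools is argued against as the cause of most of its deviations: over the 1822 probe sets where this array lay more than 1 log2 unit from the control 6 hpa mean, the median ratio of replicate 2 to replicate 1 was −0.075 (quartiles −0.247 and 0.124), while the same measure, added later, was −0.235 from replicate 2 and 0.353 to 0.628 on the 4 arrays of the other TCDD groups. Degraded or poorly amplified RNA could not be decided. The actin 3′ minus 5′ difference was 3.35 against 1.36 to 2.07 on the other replicate 1 arrays and −0.08 to 1.29 on the replicate 2 arrays. The gapdh difference of 1.12 lay within the range of all other arrays but below the 1.35 to 1.96 of the other replicate 1 arrays. A difference between the 10 hearts of this pool and those of the other was not tested and stays open as well.

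For the count of 8 probe sets called in the mean TCDD effect chance cannot be excluded: 11 of 100 splits of the arrays within times, the real one included, gave as many probe sets as the real split. This concerns the count and not cyp1a, which was higher by 8.33, 7.35 and 8.87 at the 3 times. The highest other split called 100, and it set replicate 2 at 0 and 6 hpa and replicate 1 at 7 dpa against the rest, so that it points to a structure of the samples other than treatment.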

How the results depend on the processing

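The replicate block within each time, the epidermal covariate and leaving out TCDD 6 hpa replicate 1 from comparisons without it were chosen after seeing the data. No named gene that was called changed direction under any alternative run on named genes. Of 218 calls of named genes quantile normalization kept 200, the replicate block 190, trend and robust settings 185, array weights 165 and median centring 131, of 213 a fit of the compared groups alone kept 101, and of 920 with 1 array left out 372 stayed. Dim probe sets, near the background of the array, limit what can be seen in genes of low signal, and a lone array was assumed to vary like the other groups. Unless a reason is given, the cause was not tested.

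Quantile normalization moved the counts to 156 in control 6 hpa, 499 in control 7 dpa, 514 in TCDD 6 hpa and 0 in the 6 hpa interaction. Median centring gave 22 in control 6 hpa, 131 in TCDD 6 hpa and 5 in the mean TCDD effect, and it moved the median of all probe sets in the 6 hpa interaction from 0.03 to −0.08. The share of calls that were higher went, from the values as deposited to quantile normalization to median centring, from 33.8% to 46.2% to 18.2% in control 6 hpa, from 82.6% to 68.5% to 86.5% in control 7 dpa, from 24.7% to 37.4% to 19.1% in TCDD 6 hpa, from 83.1% to 68.8% to 86.0% in TCDD 7 dpa, from 75% to 100% to 100% for TCDD at 0 hpa and from 87.5% to 100% to 80% for the mean effect. Trend and robust settings called 58 for TCDD at 7 dpa, 5 in the 7 dpa interaction and 13 in the mean effect.

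Array weights, which came out equal within each pair and lowest for TCDD 6 hpa (0.428), called 10 for TCDD at 0 hpa, 566 in control 6 hpa, 542 in control 7 dpa, 20 in TCDD 6 hpa and 602 in TCDD 7 dpa. Adjustment over all 10 comparisons together called 138 in control 7 dpa, 88 in TCDD 6 hpa, 158 in TCDD 7 dpa, 3 and 5 in the 6 hpa and 7 dpa interactions and 16 in the mean effect. With fewer arrays behind the spread, fits of only the compared groups called 0 for TCDD at 6 hpa, 2 for TCDD at 7 dpa, 23 in control 6 hpa, 0 in TCDD 6 hpa and 0 in the 6 hpa interaction (limma, where the full fit had 421, 615, 1587, 2659 and 176 at an unadjusted p under 0.05). The epidermal covariate, which overlaps with the TCDD 7 dpa group, left 2 calls for TCDD at 7 dpa, 180 in control 7 dpa, 2 in TCDD 7 dpa, 0 in the 7 dpa interaction and 3 in the mean effect. With this covariate calls can be lost through larger standard errors as well as through smaller estimates.

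The labels do not say that replicate numbers pair the samples. The correlation of replicate differences between control and TCDD was 0.48 at 0 hpa, −0.14 at 6 hpa and 0.56 at 7 dpa. The actin 3′ minus 5′ difference was higher on replicate 1 in all 6 groups, a hint from the data at a shared handling by number and not from the design. With the replicate block the count for TCDD at 7 dpa was 10, and the others were within 1.5 times of the unblocked counts. A replicate block within each time, which uses up further degrees of freedom, called 1 for TCDD at 0 hpa, 5 at 7 dpa, 0 in either interaction and 1 in the mean effect.

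Leaving out 1 array gave counts from 1 to 4 for TCDD at 0 hpa, 2 to 762 at 6 hpa, 6 to 98 at 7 dpa, 2 to 309 in control 6 hpa, 54 to 627 in control 7 dpa, 0 to 2424 in TCDD 6 hpa, 101 to 683 in TCDD 7 dpa, 0 to 120 and 0 to 31 in the 6 hpa and 7 dpa interactions and 4 to 41 in the mean effect. The correlation of TCDD effects ran from 0.023 to 0.306 between 0 and 6 hpa, 0.0787 to 0.263 between 0 hpa and 7 dpa and −0.204 to 0.151 between 6 hpa and 7 dpa. That of the amputation responses, with 1 array of the compared groups left out, ran from 0.633 to 0.789 at 6 hpa and 0.66 to 0.763 at 7 dpa. With all arrays it was 0.786 and 0.775. Of the 104 list calls among 270 tests, 9 remained with an estimated correlation and fry called 20, and with 1 array left out the total ran from 94 to 112. The fry calls were 7 in control 7 dpa, 5 in TCDD 7 dpa, 4 in TCDD 6 hpa and 2 in control 6 hpa. For TCDD at 7 dpa and for the mean effect fry called 1 list each. Without TCDD 6 hpa replicate 1 immediate early genes tested in the opposite direction for TCDD at 6 hpa (adjusted p = 0.000305) and in the 6 hpa interaction (adjusted p = 0.0295), as did oxidative phosphorylation genes in the latter (adjusted p = 0.0144). Over all arrays left out singly, the adjusted p of these 3 tests ran from 6.92e-07 to 0.221, from 7.4e-07 to 0.656 and from 1.59e-32 to 0.0144.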

Other observations

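The exocrine pancreas test was chosen after pancreas genes had been seen on 1 array, and the skeletal muscle genes were picked after their values had been seen.

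The median of 6 genes of fast skeletal muscle was highest on replicate 2 of both groups at 7 dpa, the arrays where the BioB control was highest too. For these genes (pvalb2 and pvalb4, which encode the calcium buffer parvalbumin, the myosin light chain genes mylpfa, myl1 and mylz3, and the calcium pump gene atp2a1) the lower of the 2 medians was 4.93, and the highest on any other array 3.42. On TCDD 7 dpa replicate 2 atp2a1 (2.91) and myl1 (3.06) stayed low, the former below its 2.97 on control 0 hpa replicate 1. None of the 6 passed between treatments at 7 dpa (limma adjusted p = 1 for each), with differences from −1.04 for pvalb2 to 0.83 for pvalb4.

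Genes of the exocrine pancreas were high on control 0 hpa replicate 2, the array with the 2 raised control probe sets: ctrb.1, a chymotrypsinogen, lay at 8.96, cela1.6, an elastase, at 6.75 and prss1, a trypsin, at 6.23. Pancreas tissue in the pool is a candidate source. Of 8 pancreas genes whose single values had not been looked at, 3 lay above log2 5 on some array. Their median on this array was 0.291 above the mean of the other arrays, between the bounds of 0.25 and 1 set for the test. Cpb1 and sycn.2 passed the limit only on TCDD 6 hpa replicate 1 (5.07 and 5.60), and ctrl only on control 0 hpa replicate 2 (5.40). The limit thus let in genes through another array, so the test cannot decide and the source stays open. Without this array ctrb.1 was at −2.61 in control 7 dpa against unamputated control, with an adjusted p of 0.254, and without control 7 dpa replicate 1 or 2 it was at −3.88 or −3.57 with an adjusted p of 0.149 or 0.161.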
